A study of Homo sapiens with 16 samples.

How the data were processed

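The series holds total RNA sequencing of 16 libraries from HCT116, a human colorectal carcinoma line, and U2OS, a human osteosarcoma line. Per the labels, cells were transfected with small interfering RNA (siRNA), short duplexes that lead to loss of a matching transcript, against MYBL1, MYBL2, both, or no human target (siCtrl), and RNA was taken after 48 hours with a column kit from Zymo. Libraries were made and sequenced in pairs of reads by a commercial provider, per the labels. Each of the 8 groups had 2 libraries, which the series' design text calls biological replicates. MYBL2 works with the MuvB complex, whose core also forms the repressor DREAM with other subunits.

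Adapter trimming with cutadapt 4.4, transcript quantification with Salmon 1.10.1 and gene tests with DESeq2 1.40 are named, with the build hg38, in the submitters' processing notes; the notes give no order or settings. How the authors summed transcripts to genes, the annotation they used and their filters are not given in the sources used here. The data were 6 tables of the authors' own comparisons, 1 for each knockdown against siCtrl of its line. The deposited base mean is a signal, the mean of normalized counts over the 4 libraries of a comparison, per the file headers. The deposited log2 fold change of knockdown over siCtrl has its standard error on the log2 scale. The deposited Wald statistic is a score, the fold change over its standard error. Each deposited p-value matched a normal test of that statistic, 2-sided, and the authors' adjusted p-value matched the Benjamini-Hochberg adjustment over the genes listed. The base mean of a gene differed between tables of 1 line, so each table was fitted on its own 4 libraries. Genes were listed down to a base mean that differed between tables, from 4.46 to 40.4, so low genes are missing from some tables and not from others.

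The tables hold no values per library. The read depth of each library is therefore unknown, and no replicate values, SD or intervals for single libraries are given; base means summed to 18966977, 18873216 and 19826741 in HCT116 and 17518487, 17821908 and 17441617 in U2OS, for siMYBL1, siMYBL2 and the double knockdown. The median standard error of genes with a base mean of at least 100 was 0.187, 0.204 and 0.198 in HCT116 and 0.222, 0.221 and 0.224 in U2OS. The planned fits of counts per library were replaced by the tests planned for tables alone. Against siCtrl, the authors' log2 fold change, standard error and adjusted p were used with a threshold of 0.05. Double against single knockdowns, and U2OS against HCT116, were compared by the difference of 2 log2 fold changes over the root of their summed squared standard errors, with a normal p and Benjamini-Hochberg adjustment. Within a line this error is too large, because the shared controls cancel. The departure of the double knockdown from the sum of the single ones was planned only for values per library; it was computed from 3 tables after the data were examined, with the variances summed.

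Gene lists were fixed before the data were examined, as were the tests, thresholds and the rule for naming genes. They held 75 late cell cycle (G2/M), 60 G1/S E2F-target, 58 replication-dependent histone, 36 p53 target, 13 MYB family, MuvB and DREAM, 44 germline, 40 interferon-stimulated, 25 cholesterol synthesis, 32 unfolded protein and amino acid stress, 31 senescence-associated secretory, 75 cytosolic ribosomal protein, 15 mitochondrially encoded, 20 epithelial, 22 mesenchymal and 16 blood cell genes. The MYB family, MuvB and DREAM list held MYB and left out the targets MYBL1 and MYBL2. FOXM1 stands in the G2/M and MuvB lists and SESN2 in the p53 and stress lists. Lists with at least 3 listed members were tested with cameraPR of limma on the Wald statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation estimated from the data needs values per library; 0.05 was used as the alternative. Counts of members adjusted over the list alone repeat the Benjamini-Hochberg adjustment within the list.

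MYB, MYBL1 and MYBL2 were always named. The rule then took the 6 higher and 6 lower genes with the largest change among those with adjusted p under 0.05 and a base mean of at least 100, up to 4 members with the smallest adjusted p of the G2/M, G1/S, p53, MuvB and germline lists, and up to 2 of each other list. For double against single knockdowns it took 4 higher, 4 lower and up to 4 G2/M genes. CDK1, CCNB1, PLK1, AURKA, TOP2A and CDKN1A could be named anywhere, and a gene named once could be named in any comparison. Values of some genes that the rule takes are not reported here. Histone genes and the FAM72 family have near-identical copies, so their values are uncertain. Coordinates come from the annotation of hg38 used here (release 29), which need not be the authors' release.

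To see what shared controls alone give, unchanged groups were simulated against the same controls in 100 draws, leaving out genes with a standard error above 2. After the data were examined, 3′ UTRs of at least 20 bases (19054 genes) were searched for 15375 words of 7 bases held by at least 100 genes and missing from at least 100. For 9839 genes with a base mean of at least 100 in all 6 tables and a standard error below 2, the Wald statistic, limited to plus or minus 8, was regressed on presence of the word with length and GC content as covariates. The siRNA sequences are not given in the sources used here.

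The gene tests, the list test and the search for 7-mers were run on simulated data. For the U2OS double knockdown (16751 genes), changes of 0.5, 1 and 2 on the log2 scale were recovered in 10.4%, 59.7% and 80.3% of changed genes, with 5 unchanged genes called. For the U2OS double against siMYBL2 (15440 genes), changes of 1 and 2 were recovered in 30% and 83%, with 0 unchanged genes called by the normal test and 0.604% of them at an unadjusted p under 0.05. With an assumed correlation of 0.5 these were 66% and 93%, with 14 unchanged genes called. For the departure of the U2OS double knockdown from the sum of the single ones (14670 genes), changes of 1 and 2 were recovered in 11% and 68%, with 0 unchanged genes called and 1.60% of them at an unadjusted p under 0.05. For U2OS against HCT116 in the double knockdown (12365 genes) these were 40% and 89%, with 7 unchanged genes called and 5.07% at an unadjusted p under 0.05. The list test called a list in 1 of 50 draws without change and recovered 13 of 20 lists shifted by 0.5 standard errors. Genes were independent of each other in these draws. They therefore do not show how often lists whose members vary together are called without change. In the search for 7-mers (9839 genes), a planted word carried by 1033 genes ranked 1 and passed when all carriers were lowered by 0.25 standard errors or more, or 258 by 1 or more. It did not pass with 258 lowered by 0.5, where it ranked 81. With 60 lowered by 2 it did not pass in either draw, ranking 1 and 66; the draw ranking 66 was the first one made. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. Alternatives were stricter thresholds, minimum base means of 10 and 100, the list test on log2 fold changes, on ranks and with a correlation of 0.05, and, added after the data were examined, the authors' call column, genes without the siRNA-associated 6-mers and a correlation of 0.5 between comparisons.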

Results

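RNA was measured by paired-end sequencing in 16 libraries from 2 human cell lines, HCT116 (a colorectal carcinoma line) and U2OS (an osteosarcoma line). Each line was transfected with a non-targeting small interfering RNA (siCtrl), with siRNA against MYBL1, with siRNA against MYBL2, or with both targeting siRNAs together (the double knockdown), and collected after 48 hours. Each of the 8 groups held 2 libraries, labelled as biological replicates. MYBL1 (A-MYB) and MYBL2 (B-MYB) are transcription factors of the MYB family, and MYBL2 joins the MuvB complex at promoters of genes that peak in G2 and mitosis. The comparisons asked which genes depend on each factor, and whether losing both differs from losing 1. The data were 6 gene tables, each comparing 1 knockdown with siCtrl of the same line. The normalized counts in a table, averaged over its 4 libraries, summed to between 17441617 and 19826741 over the listed genes, and the depth of single libraries was not known here. Values are log2 fold changes of knockdown over siCtrl with their standard errors (SE), positive where the knockdown was higher.

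The targets were examined first. In HCT116 the authors' deposited table put MYBL2 (chromosome 20, positions 43667019 to 43716495 of hg38, forward strand) at -3.47 (SE 0.18, adjusted p = 2.56e-74) after siMYBL2 and at -3.33 (SE 0.17, adjusted p = 1.11e-82) in the double knockdown. These changes correspond to 9.05% and 9.92% of the control level. The fall in U2OS was larger, with -4.47 (SE 0.18, adjusted p = 1.28e-133) after siMYBL2 and -4.53 (SE 0.18, adjusted p = 5.19e-134) in the double knockdown in the authors' deposited table, or 4.53% and 4.34% of control. MYBL1 (chromosome 8, positions 66562175 to 66614247 of hg38, reverse strand) fell after siMYBL1 to -1.67 (SE 0.32, adjusted p = 0.000267) in HCT116 and to -0.98 (SE 0.31, adjusted p = 0.0300) in U2OS in the authors' deposited table. In the double knockdown, the authors' deposited table placed MYBL1 at -1.85 (SE 0.37, adjusted p = 4.24e-05) in HCT116 and -1.20 (SE 0.34, adjusted p = 0.00497) in U2OS. MYBL1 retained 31.4% of the control level in HCT116 and 50.7% in U2OS after siMYBL1, a larger remainder than that of MYBL2 after siMYBL2. Neither single siRNA moved the other target past the threshold. MYBL2 stood at -0.03 (SE 0.15, adjusted p = 1) in HCT116 and -0.29 (SE 0.19, adjusted p = 0.449) in U2OS after siMYBL1, and MYBL1 at -0.40 (SE 0.27, adjusted p = 0.849) and -0.21 (SE 0.27, adjusted p = 0.879) after siMYBL2, in the authors' deposited table. The third family member, MYB, did not pass in any of the comparisons with siCtrl, and the authors' deposited table gave -0.44 (SE 0.31, adjusted p = 0.504) in HCT116 and 0.92 (SE 0.42, adjusted p = 0.157) in U2OS for the double knockdown.

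**Figure D1:**
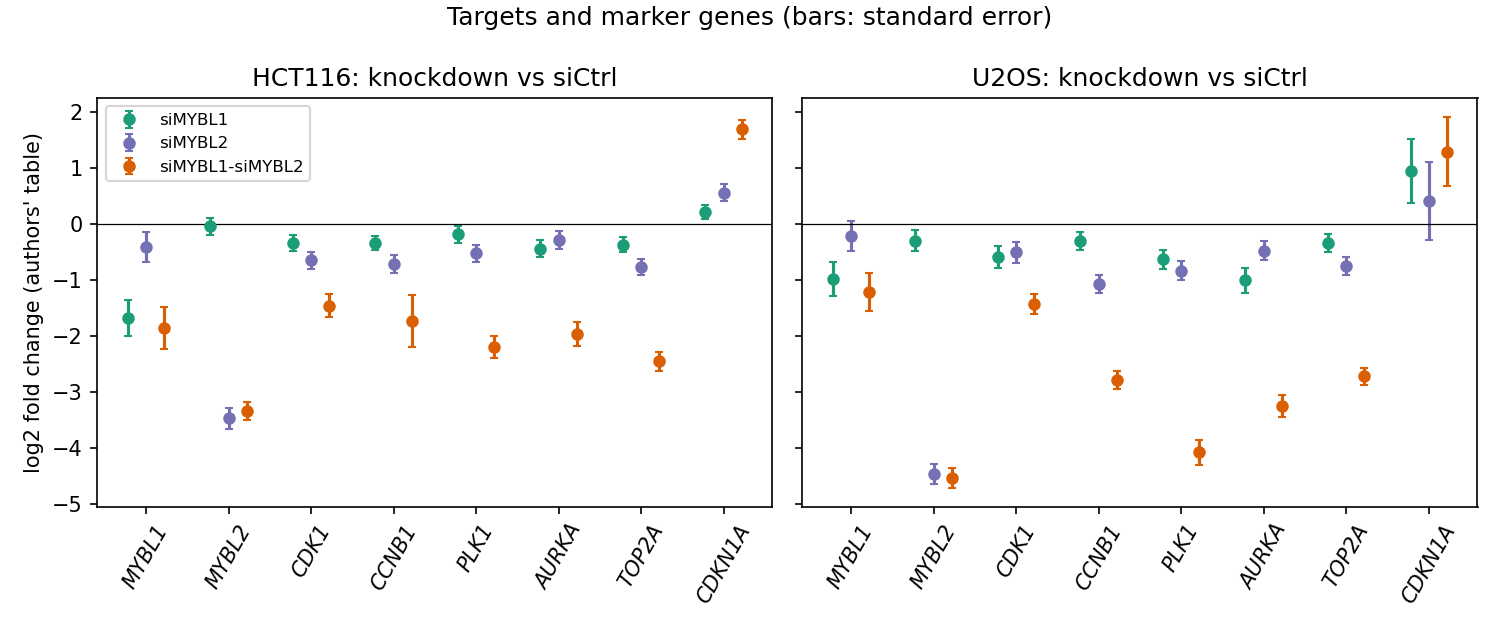
Log2 fold changes of MYBL1, MYBL2 and 6 marker genes after each knockdown against siCtrl, in HCT116 (left) and U2OS (right). The values are those of the authors' deposited table and bars are standard errors. PLK1 lay at -2.19 in HCT116 and -4.07 in U2OS in the double knockdown, below both single knockdowns in each line.

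After siMYBL1 in HCT116, 45 genes changed. Among those with a base mean of at least 100, apart from MYBL1, PPIC, a cyclophilin, fell to -1.58 (SE 0.25, adjusted p = 1.80e-06) and LMNB1, which encodes lamin B1 of the nuclear envelope, to -1.27 (SE 0.15, adjusted p = 3.43e-12) in the authors' deposited table. The next lower genes in the authors' deposited table were GINM1 at -1.19 (SE 0.21), LPCAT2 at -1.19 (SE 0.24) and USP30 at -1.09 (SE 0.27). By the same minimum the highest were KLK10, a secreted serine protease, at 1.12 (SE 0.25, adjusted p = 0.00602), and F3, the tissue factor that starts coagulation, at 0.94 (SE 0.24, adjusted p = 0.0391) in the authors' deposited table. Of 17323 genes listed, 45 passed, 20 higher and 25 lower, and 791 had an unadjusted p under 0.05. The 3′ UTRs of PPIC, LMNB1, GINM1 and LPCAT2 held the 7-base sequence described below as associated with siMYBL1. Genes are marked in this way only for the sequence ranked first after an siRNA, so an unmarked gene may hold another associated sequence.

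LMNB1 was the single member of the late cell cycle (G2/M) list to pass in HCT116 after siMYBL1. Of 75 listed members, 1 was lower and 74 were not called (1 lower adjusted over the list alone). Other G2/M members did not pass singly, such as NEK2 at -0.53 (SE 0.19), AURKA at -0.43 (SE 0.15) and TOP2A at -0.36 (SE 0.13) in the authors' deposited table. The list together lay below other genes (median -0.21, adjusted p = 1.00e-22). Histone genes were also low as a list (median -0.74, adjusted p = 0.000238), although their counts were small. Of 42 listed members, 1 was lower and 41 were not called (1 lower adjusted over the list alone). That gene was H4C15, at -7.23 (SE 1.74) with a base mean of 14.3 in the authors' deposited table, and it shares near-identical copies with other histone genes. Senescence-associated secretory genes (median 0.37, adjusted p = 2.37e-05) and mitochondrially encoded genes (median 0.25, adjusted p = 6.65e-08; adjusted p = 0.257 on log2 fold changes) lay above other genes. For the secretory genes, 0 of 21 listed members passed the Wald test, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone; for the mitochondrial genes, 0 of 15 listed members passed the Wald test, 6 had an unadjusted p under 0.05 and 5 higher passed adjusted over the list alone. G1/S E2F-target genes (median -0.07, adjusted p = 0.00458; adjusted p = 0.120 with a correlation of 0.05 and 0.937 on log2 fold changes), cytosolic ribosomal protein genes (median -0.05, adjusted p = 0.00191; adjusted p = 0.112 with a correlation of 0.05 and 0.937 on log2 fold changes), cholesterol synthesis genes (median 0.07, adjusted p = 0.0485; adjusted p = 0.187 with a correlation of 0.05 and 0.937 on log2 fold changes) and unfolded protein and amino acid stress genes (median 0.14, adjusted p = 0.0482; adjusted p = 0.187 with a correlation of 0.05 and 0.937 on log2 fold changes) passed the list test at its preset correlation. The p53 targets did not (median 0.02, adjusted p = 0.807), nor did epithelial markers (median 0.07, adjusted p = 0.516). The mean and median differed in sign for mesenchymal markers (-0.18 and 0.13, adjusted p = 0.883) and blood cell markers (0.09 and -0.20, adjusted p = 0.883), with the test upward in each. Germline genes had a mean of -0.04, also with an upward test (adjusted p = 0.883).

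After siMYBL2 in HCT116, 35 of the 112 genes that fell belonged to the G2/M list. PIF1, a DNA helicase, fell to -1.67 (SE 0.31, adjusted p = 3.68e-05), and DEPDC1B to -1.20 (SE 0.20, adjusted p = 1.71e-06) in the authors' deposited table. The spindle genes DLGAP5 at -0.90 (SE 0.16, adjusted p = 1.87e-05) and SPC25 at -1.14 (SE 0.21, adjusted p = 2.91e-05) also fell in the authors' deposited table, as did TOP2A at -0.76 (SE 0.15, adjusted p = 0.000143). In the authors' deposited table CCNB1 fell to -0.71 (SE 0.16, adjusted p = 0.00213) and CDK1 to -0.64 (SE 0.15, adjusted p = 0.00434), whereas PLK1 at -0.51 (SE 0.15, adjusted p = 0.0607) and AURKA at -0.28 (SE 0.16, adjusted p = 0.739) did not pass. Outside the list the lower genes in the authors' deposited table included ZNF468 at -1.55 (SE 0.32), SLAIN2 at -1.44 (SE 0.25), TSPAN9 at -1.41 (SE 0.25) and NUMB at -1.36 (SE 0.20), and the 3′ UTR of each of these 4 held the 7-mer described below as associated with siMYBL2. With a base mean of at least 100, the rises in the authors' deposited table were led by DRAXIN at 1.75 (SE 0.39, adjusted p = 0.00174), SMAD7, an inhibitor of TGF-beta signalling, at 1.68 (SE 0.48, adjusted p = 0.0455), and PADI3 at 1.67 (SE 0.40, adjusted p = 0.00560).

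In all, 151 of 13387 listed genes passed after siMYBL2 in HCT116, 39 higher and 112 lower, with 1080 at an unadjusted p under 0.05. For the G2/M list, of 75 listed members, 35 were lower and 40 were not called (53 lower adjusted over the list alone), and the list lay below other genes (median -0.56, adjusted p = 2.24e-67). For the G1/S list, of 60 listed members, 2 were lower and 58 were not called (2 lower adjusted over the list alone); UHRF1 stood at -0.64 (SE 0.16, adjusted p = 0.00746) and RRM2 at -0.53 (SE 0.14, adjusted p = 0.0203) in the authors' deposited table, and the list had a median of -0.18 (adjusted p = 3.32e-06). For p53 targets, of 33 listed members, 2 were higher and 31 were not called (2 higher and 2 lower adjusted over the list alone), and the list lay above other genes (median 0.23, adjusted p = 1.80e-05). BTG2 rose to 0.90 (SE 0.22, adjusted p = 0.00494) and CDKN1A, the cyclin-dependent kinase inhibitor p21, to 0.57 (SE 0.15, adjusted p = 0.0230) in the authors' deposited table. DDX58, the RNA sensor RIG-I, was the single interferon-stimulated gene to rise (1.07 (SE 0.29, adjusted p = 0.0292) in the authors' deposited table), and its list lay above other genes (median 0.29, adjusted p = 6.20e-05). Stress genes lay below other genes as a list (median -0.26, adjusted p = 4.36e-05). Of 31 listed members, 1 was lower and 30 were not called (2 lower adjusted over the list alone), and ASNS, asparagine synthetase, was the single member called, at -0.86 (SE 0.18, adjusted p = 0.000947) in the authors' deposited table. Cholesterol synthesis genes lay below other genes as a list (median -0.16, adjusted p = 0.00772; adjusted p = 0.0569 with a correlation of 0.05 and 0.0735 on log2 fold changes). Of 25 listed members, 1 was lower and 24 were not called (1 lower adjusted over the list alone). Of the 21 searched members of that list without the 6-base sequence described below as associated with siMYBL2, 0 were lower. Mitochondrially encoded genes (median 0.37, adjusted p = 1.80e-05) and mesenchymal markers (median 0.39, adjusted p = 0.000241) lay above other genes, while epithelial markers (median 0.14, adjusted p = 0.0896) and secretory genes, with a mean of -0.01 (adjusted p = 0.655), did not pass. For histone genes the median was -0.50 and the mean -0.27, while the test pointed upward (adjusted p = 0.585; adjusted p = 0.00457 downward on log2 fold changes).

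In the HCT116 double knockdown, nearly the whole G2/M list fell. PIF1, whose 3′ UTR held the 7-mer associated with siMYBL1, fell to -3.15 (SE 0.34, adjusted p = 3.31e-18) and CKAP2L, a spindle protein, to -2.71 (SE 0.22, adjusted p = 1.53e-30) in the authors' deposited table. CDCA3 stood at -2.68 (SE 0.24, adjusted p = 8.74e-26) and CENPE, a kinetochore motor whose 3′ UTR held the 7-mer associated with siMYBL2, at -2.67 (SE 0.24, adjusted p = 7.77e-25) in the authors' deposited table. The mitotic kinases PLK1 and AURKA fell to -2.19 (SE 0.20, adjusted p = 1.80e-25) and -1.96 (SE 0.22, adjusted p = 1.21e-16), TOP2A to -2.45 (SE 0.17, adjusted p = 3.65e-42) and MKI67 to -2.34 (SE 0.18, adjusted p = 6.79e-34) in the authors' deposited table. FAM72D, at -2.69 (SE 0.30) in the authors' deposited table, belongs to a family of near-identical copies, so its value is uncertain. Genes that rose included the protease gene CPA4 at 2.45 (SE 0.26, adjusted p = 1.43e-18), PTAFR at 2.45 (SE 0.36, adjusted p = 1.23e-09), ACTA2 at 2.32 (SE 0.39, adjusted p = 2.39e-07) and the p53 targets BTG2 at 1.95 (SE 0.23, adjusted p = 3.56e-15) and CDKN1A at 1.70 (SE 0.17, adjusted p = 8.53e-21), in the authors' deposited table.

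Of 12885 genes listed for the HCT116 double knockdown, 895 passed, 364 higher and 531 lower, and 2390 had an unadjusted p under 0.05. For the G2/M list, of 75 listed members, 74 were lower and 1 was not called (74 lower adjusted over the list alone), with a median of -1.69 (adjusted p = 2.94e-207). For the G1/S list, of 60 listed members, 29 were lower and 31 were not called (46 lower adjusted over the list alone), with a median of -0.53 (adjusted p = 2.55e-25); RRM2, a subunit of ribonucleotide reductase, fell to -1.18 (SE 0.15, adjusted p = 5.73e-13) in the authors' deposited table. For p53 targets, of 33 listed members, 22 were higher and 11 were not called (26 higher adjusted over the list alone), with a median of 0.68 (adjusted p = 3.55e-31). TP53I3 at 1.70 (SE 0.24, adjusted p = 1.06e-10) and FDXR at 1.06 (SE 0.16, adjusted p = 4.94e-09) were further p53 targets that rose in the authors' deposited table. Among MYB family, MuvB and DREAM subunits without MYBL1 and MYBL2 (median -0.39, adjusted p = 0.0114), FOXM1, a transcription factor of the G2/M programme, fell to -0.97 (SE 0.17, adjusted p = 2.59e-06) in the authors' deposited table. Senescence-associated secretory genes were higher (median 0.39, adjusted p = 0.000120). Of 12 listed members, 3 were higher and 9 were not called (4 higher adjusted over the list alone). Mitochondrially encoded genes were higher (median 0.40, adjusted p = 0.000165). Of 15 listed members, 4 were higher and 11 were not called (6 higher adjusted over the list alone). Cholesterol synthesis genes were lower (median -0.30, adjusted p = 0.000622). Of 25 listed members, 4 were lower and 21 were not called (7 lower adjusted over the list alone). Interferon-stimulated genes (median 0.20, adjusted p = 0.0271; adjusted p = 0.107 with a correlation of 0.05) and mesenchymal markers (median 0.34, adjusted p = 0.0461; adjusted p = 0.0981 with a correlation of 0.05) passed at the preset correlation. Epithelial markers did not pass as a list (median 0.19, adjusted p = 0.0663), and ribosomal protein genes (median -0.08, adjusted p = 0.0845) and stress genes (median -0.15, adjusted p = 0.0663) did not either. For germline genes the median was 0.06 and the mean -0.02 (adjusted p = 0.912), and for histone genes -0.02 and -0.29 while the test pointed upward (adjusted p = 0.164).

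After siMYBL1 in U2OS, LMNB1 fell furthest among genes with a base mean of at least 100, to -2.29 (SE 0.18, adjusted p = 4.21e-34) in the authors' deposited table. It was followed by ENPP4 at -1.98 (SE 0.30), PDCD5 at -1.97 (SE 0.26), PPIC at -1.97 (SE 0.21), OIP5 at -1.95 (SE 0.32) and ZNF80 at -1.76 (SE 0.37) in the authors' deposited table, and the 3′ UTRs of all 6 genes held the 7-mer associated with siMYBL1. Genes that rose included INHBE at 3.90 (SE 1.103, adjusted p = 0.0127), TRAF1 at 2.91 (SE 0.35, adjusted p = 3.68e-13), GDF15, a stress-induced cytokine, at 2.85 (SE 0.77, adjusted p = 0.00823) and the keratin gene KRT34 at 2.65 (SE 0.45, adjusted p = 1.70e-06) in the authors' deposited table. H2AC19 was listed at 23.52 (SE 4.79) in the authors' deposited table, but it has a near-identical copy in H2AC18, and this value is uncertain. Among stress genes, DDIT4 rose to 1.67 (SE 0.25, adjusted p = 1.57e-08) and HERPUD1 to 1.52 (SE 0.25, adjusted p = 5.34e-07) in the authors' deposited table.

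Of 14763 genes listed after siMYBL1 in U2OS, 843 passed, 508 higher and 335 lower, with 2489 at an unadjusted p under 0.05. For the G2/M list, of 75 listed members, 32 were lower and 43 were not called (57 lower adjusted over the list alone), with a median of -0.52 (adjusted p = 1.15e-38); HMMR fell to -1.05 (SE 0.19, adjusted p = 4.69e-06), AURKA to -0.9982 (SE 0.22, adjusted p = 0.000585) and PLK1 to -0.62 (SE 0.17, adjusted p = 0.00859) in the authors' deposited table, while CCNB1 at -0.29 (SE 0.16, adjusted p = 0.334) did not pass. For the G1/S list, of 60 listed members, 11 were lower and 49 were not called (27 lower adjusted over the list alone), with a median of -0.40 (adjusted p = 1.55e-18). Stress genes were higher (median 0.70, adjusted p = 9.45e-18). Of 32 listed members, 17 were higher and 15 were not called (22 higher adjusted over the list alone). The p53 targets were higher (median 0.49, adjusted p = 2.47e-09). Of 35 listed members, 7 were higher and 28 were not called (14 higher adjusted over the list alone), with SESN2 at 1.55 (SE 0.27, adjusted p = 2.66e-06) and GADD45A at 1.18 (SE 0.23, adjusted p = 6.89e-05), whereas CDKN1A at 0.96 (SE 0.57, adjusted p = 0.414) did not pass in the authors' deposited table. Senescence-associated secretory genes were higher (median 0.97, adjusted p = 2.85e-10). Of 19 listed members, 9 were higher and 10 were not called (11 higher adjusted over the list alone), with HBEGF, an epidermal growth factor receptor ligand, at 1.57 (SE 0.22, adjusted p = 4.06e-10) in the authors' deposited table. Cholesterol synthesis genes were higher (median 0.37, adjusted p = 1.09e-09). Of 24 listed members, 7 were higher and 17 were not called (11 higher and 1 lower adjusted over the list alone), with MSMO1 at 1.04 (SE 0.19, adjusted p = 7.58e-06) in the authors' deposited table. Mesenchymal markers were higher (median 0.34, adjusted p = 0.000795). Of 18 listed members, 2 were higher and 16 were not called (5 higher adjusted over the list alone), the collagen genes COL6A3 and COL1A1 at 1.35 (SE 0.22, adjusted p = 2.54e-07) and 0.73 (SE 0.16, adjusted p = 0.000514) in the authors' deposited table. Blood cell markers were higher too (median 1.17, adjusted p = 0.000795). Of 3 listed members, 2 were higher and 1 was not called (2 higher adjusted over the list alone), with CSF1R at 2.74 (SE 0.65, adjusted p = 0.00165) and CORO1A at 1.17 (SE 0.31, adjusted p = 0.00788) in the authors' deposited table. Interferon-stimulated genes (median -0.24, adjusted p = 0.0175; adjusted p = 0.0929 with a correlation of 0.05), ribosomal protein genes (median -0.09, adjusted p = 0.0135; adjusted p = 0.134 with a correlation of 0.05 and 0.206 on log2 fold changes) and mitochondrially encoded genes (median 0.19, adjusted p = 0.0227; adjusted p = 0.0832 with a correlation of 0.05 and 0.238 on log2 fold changes) passed at the preset correlation. IFIT1, an antiviral gene, fell to -1.70 (SE 0.35, adjusted p = 0.000149) in the authors' deposited table. Epithelial markers had a median of 0.06 and a mean of 0.25 while the test pointed downward (adjusted p = 0.781).

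After siMYBL2 in U2OS, G2/M genes fell and several genes outside the cell cycle fell further. ANO2 stood at -2.99 (SE 0.27, adjusted p = 1.50e-24), the alkaline phosphatase gene ALPP at -2.94 (SE 0.29, adjusted p = 5.21e-21) and DAP at -2.59 (SE 0.19, adjusted p = 2.01e-38) in the authors' deposited table; the 3′ UTR of DAP held the 7-mer associated with siMYBL2. Within the G2/M list, DEPDC1B fell to -1.88 (SE 0.21, adjusted p = 1.80e-16), PIF1 to -1.73 (SE 0.20, adjusted p = 2.93e-14), DLGAP5 to -1.41 (SE 0.16, adjusted p = 7.96e-16) and CENPE, whose 3′ UTR held the same 7-mer, to -1.58 (SE 0.18, adjusted p = 7.85e-16) in the authors' deposited table. CCNB1 stood at -1.06 (SE 0.15, adjusted p = 2.01e-09) and PLK1 at -0.82 (SE 0.17, adjusted p = 7.24e-05), whereas CDK1 at -0.50 (SE 0.19, adjusted p = 0.116) and AURKA at -0.47 (SE 0.17, adjusted p = 0.0859) did not pass in the authors' deposited table. SYTL5 at 2.14 (SE 0.36, adjusted p = 5.83e-07) and GNG11, a G protein subunit, at 1.638 (SE 0.21, adjusted p = 3.44e-12) were among the rises in the authors' deposited table.

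Of 15478 genes listed after siMYBL2 in U2OS, 805 passed, 262 higher and 543 lower, and 2212 had an unadjusted p under 0.05. For the G2/M list, of 75 listed members, 44 were lower and 31 were not called (55 lower adjusted over the list alone), with a median of -0.66 (adjusted p = 6.60e-57). For the G1/S list, of 60 listed members, 1 was higher, 5 were lower and 54 were not called (1 higher and 8 lower adjusted over the list alone), with a median of -0.14 (adjusted p = 0.00549; adjusted p = 0.0986 with a correlation of 0.05 and 0.111 on log2 fold changes). UHRF1, which maintains DNA methylation, fell to -1.14 (SE 0.17, adjusted p = 8.47e-09), whereas CCNE2, cyclin E2, rose to 1.19 (SE 0.29, adjusted p = 0.00235) in the authors' deposited table. Histone genes were lower (median -0.57, adjusted p = 3.73e-06). Of 28 listed members, 3 were lower and 25 were not called (8 lower adjusted over the list alone), with H2AC6 at -1.04 (SE 0.19, adjusted p = 6.74e-06) in the authors' deposited table. Cholesterol synthesis genes were lower (median -0.29, adjusted p = 0.000135). Of 24 listed members, 4 were lower and 20 were not called (5 lower adjusted over the list alone). The p53 targets were higher (median 0.30, adjusted p = 0.000225). Of 35 listed members, 3 were higher and 32 were not called (4 higher adjusted over the list alone). Interferon-stimulated genes (median 0.26, adjusted p = 0.0109; adjusted p = 0.0957 with a correlation of 0.05) and mitochondrially encoded genes (median 0.19, adjusted p = 0.0102; adjusted p = 0.0548 with a correlation of 0.05 and 0.235 on log2 fold changes) passed at the preset correlation. Secretory genes (median 0.17, adjusted p = 0.507), stress genes (median -0.20, adjusted p = 0.100), ribosomal protein genes (median -0.04, adjusted p = 0.507), epithelial markers (median -0.29, adjusted p = 0.230) and mesenchymal markers (median 0.02, adjusted p = 0.507) did not pass as lists. VIM, vimentin, fell to -0.46 (SE 0.15, adjusted p = 0.0376) in the authors' deposited table.

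In the U2OS double knockdown, mitotic genes were among those with the largest falls. PIF1, whose 3′ UTR held the 7-mer associated with siMYBL1, fell to -4.63 (SE 0.24, adjusted p = 9.48e-78), CDCA3 to -4.16 (SE 0.21, adjusted p = 2.11e-86) and PLK1 to -4.07 (SE 0.22, adjusted p = 1.69e-70) in the authors' deposited table. KIF20A, a kinesin of cytokinesis, fell to -3.64 (SE 0.18, adjusted p = 3.92e-88), AURKA to -3.24 (SE 0.19, adjusted p = 1.30e-62), CCNB1 to -2.78 (SE 0.16, adjusted p = 1.76e-61) and TOP2A to -2.71 (SE 0.16, adjusted p = 4.09e-64) in the authors' deposited table. MYOCD, a muscle transcription cofactor outside the list, fell to -3.83 (SE 0.43, adjusted p = 9.23e-17) in the authors' deposited table. TMEM265 rose to 7.31 (SE 0.95, adjusted p = 2.14e-12), the chemokine gene CXCL8 to 3.80 (SE 0.52, adjusted p = 3.88e-11) and RGS4 to 3.23 (SE 0.42, adjusted p = 3.27e-12) in the authors' deposited table. GDF15 stood at 3.08 (SE 0.70, adjusted p = 0.000252), while CDKN1A at 1.30 (SE 0.62, adjusted p = 0.179) did not pass in the authors' deposited table.

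Of 16803 genes listed for the U2OS double knockdown, 2119 passed, 1100 higher and 1019 lower, with 3876 at an unadjusted p under 0.05. For the G2/M list, of 75 listed members, 74 were lower and 1 was not called (74 lower adjusted over the list alone), with a median of -2.14 (adjusted p = 3.64e-293). The G1/S list had a median nearer 0 (median -0.12, adjusted p = 0.0227; adjusted p = 0.185 with a correlation of 0.05 and 0.227 on log2 fold changes). Of 60 listed members, 8 were lower and 52 were not called (8 lower adjusted over the list alone). The p53 targets were higher (median 0.71, adjusted p = 4.06e-14). Of 35 listed members, 19 were higher and 16 were not called (23 higher adjusted over the list alone), with SESN2 at 1.55 (SE 0.21, adjusted p = 2.06e-11) and BTG2 at 1.46 (SE 0.25, adjusted p = 3.70e-07) in the authors' deposited table. Secretory genes were higher (median 1.29, adjusted p = 1.32e-09). Of 23 listed members, 14 were higher, 1 was lower and 8 were not called (15 higher and 1 lower adjusted over the list alone). Histone genes were lower (median -1.03, adjusted p = 7.44e-06). Of 33 listed members, 9 were lower and 24 were not called (12 lower adjusted over the list alone), with H4C14 at -1.03 (SE 0.19, adjusted p = 1.54e-06) in the authors' deposited table. Among MYB family, MuvB and DREAM subunits without MYBL1 and MYBL2 (median -0.10, adjusted p = 0.0539), FOXM1 fell to -1.22 (SE 0.17, adjusted p = 1.93e-11), LIN9 to -0.71 (SE 0.25, adjusted p = 0.0409) and RBL2, the pocket protein p130 and a carrier of the 7-mer associated with siMYBL1, to -0.57 (SE 0.20, adjusted p = 0.0381) in the authors' deposited table. Mesenchymal markers were higher (median 0.49, adjusted p = 0.00311; adjusted p = 0.0710 on log2 fold changes). Of 19 listed members, 9 were higher, 1 was lower and 9 were not called (9 higher and 1 lower adjusted over the list alone). Blood cell markers were higher (median 1.55, adjusted p = 0.00463). Of 4 listed members, 2 were higher and 2 were not called (3 higher adjusted over the list alone), with CORO1A at 1.85 (SE 0.29, adjusted p = 1.93e-08) and LCP1, whose 3′ UTR held the 7-mer associated with siMYBL1, at 1.25 (SE 0.44, adjusted p = 0.0404) in the authors' deposited table. Stress genes (median 0.20, adjusted p = 0.0227; adjusted p = 0.149 with a correlation of 0.05 and 0.119 on log2 fold changes) and ribosomal protein genes (median -0.13, adjusted p = 0.0354; adjusted p = 0.241 with a correlation of 0.05 and 0.298 on log2 fold changes) passed at the preset correlation. Interferon-stimulated genes did not pass (median 0.32, adjusted p = 0.106) and held members that moved apart. Of 31 listed members, 6 were higher, 1 was lower and 24 were not called (6 higher and 3 lower adjusted over the list alone), IFIT1 at -2.43 (SE 0.32, adjusted p = 8.58e-12) and IRF1 at 1.09 (SE 0.24, adjusted p = 0.000212) in the authors' deposited table. Germline genes did not pass (median -0.12, adjusted p = 0.397) although MSH5 fell to -0.95 (SE 0.25, adjusted p = 0.00193) and DMC1, the meiotic recombinase, to -1.89 (SE 0.65, adjusted p = 0.0349) in the authors' deposited table. Mitochondrially encoded genes (median 0.13, adjusted p = 0.183), cholesterol synthesis genes (median 0.01, adjusted p = 0.861) and epithelial markers (median -0.33, adjusted p = 0.345) did not pass.

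**Figure D2:**
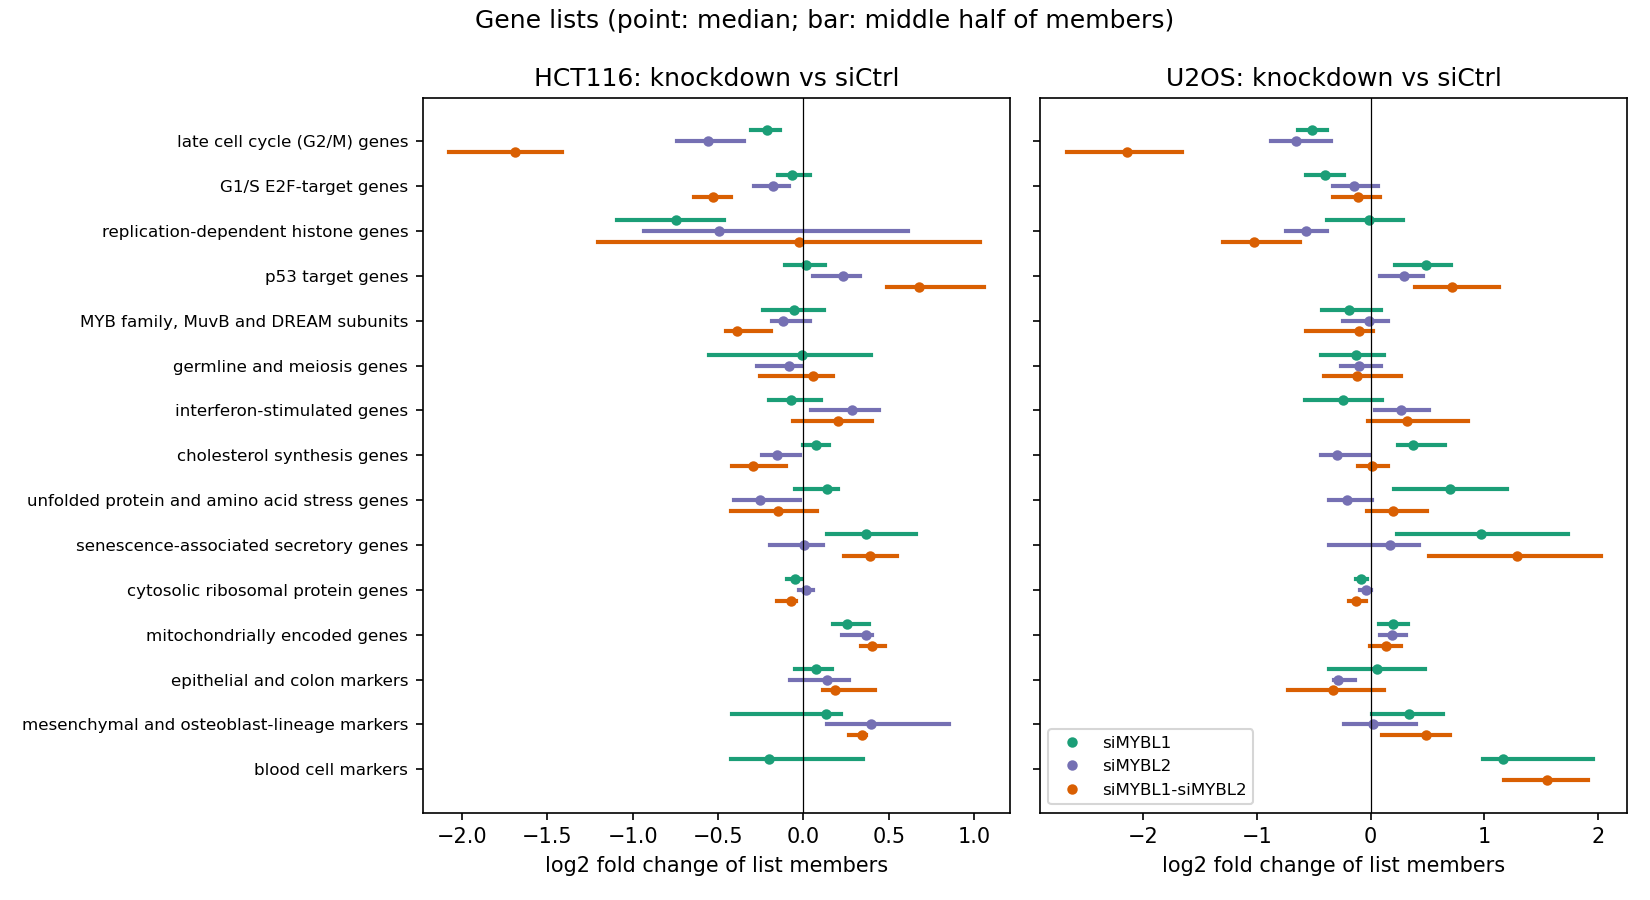
Log2 fold changes of the members of 15 gene lists against siCtrl, in HCT116 (left) and U2OS (right). Points are medians over the listed members and bars span the middle 50% of members; the scales of both panels differ. The G2/M median lay at -1.69 in HCT116 and -2.14 in U2OS in the double knockdown.

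The double knockdown was set against each single knockdown by the difference of log2 fold changes, with a standard error that treats them as independent. Against siMYBL2 in HCT116, CKAP2L differed by a further -2.16 (SE 0.30, adjusted p = 1.37e-09), KIF20A by -1.92 (SE 0.28, adjusted p = 1.08e-08) and PLK1 by -1.68 (SE 0.25, adjusted p = 2.80e-08), while CPA4 was higher by 2.83 (SE 0.42, adjusted p = 2.11e-08) and CDKN1A by 1.13 (SE 0.23, adjusted p = 0.000308). MYBL2 itself differed by 0.13 (SE 0.25, adjusted p = 1) and MYBL1 by -1.44 (SE 0.46, adjusted p = 0.189). Of 12873 genes, 83 passed, 13 higher and 70 lower, with 418 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 46 were lower and 29 were not called (66 lower adjusted over the list alone), with a median of -1.11 (adjusted p = 3.01e-209). Against siMYBL2 in U2OS, DEPDC1 differed by a further -3.44 (SE 0.31, adjusted p = 1.23e-24), PLK1 by -3.24 (SE 0.28, adjusted p = 1.84e-27) and HMMR by -2.92 (SE 0.27, adjusted p = 3.01e-24), while KRTAP2-3 was higher by 2.76 (SE 0.42, adjusted p = 2.55e-08). There 163 of 15476 genes passed, 40 higher and 123 lower (311 and 325 with an assumed correlation of 0.5 between the fold changes), with 862 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 59 were lower and 16 were not called (69 lower adjusted over the list alone), with a median of -1.40 (adjusted p = 3.44e-298). LMNB1, which carries the 7-mer associated with siMYBL1, was among the lower genes in both lines, at -1.84 (SE 0.24) and -2.55 (SE 0.22). The p53 targets lay above other genes in HCT116 (median 0.58, adjusted p = 2.14e-27) and U2OS (median 0.42, adjusted p = 8.24e-10), as did secretory genes (median 0.52, adjusted p = 2.73e-10 and median 0.81, adjusted p = 9.73e-09). In U2OS, stress genes (median 0.36, adjusted p = 1.03e-07), cholesterol synthesis genes (median 0.33, adjusted p = 9.66e-06) and mesenchymal markers (median 0.25, adjusted p = 0.000876) lay above other genes as well. In HCT116 these lists did not pass (adjusted p = 0.236, adjusted p = 0.0600 and adjusted p = 0.857). The G1/S list lay below other genes in HCT116 (median -0.35, adjusted p = 4.78e-21), and in U2OS its median of 0.02 and mean of -0.01 differed in sign (adjusted p = 0.896).

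Against siMYBL1 in HCT116, the double knockdown differed for PRR11 by a further -2.61 (SE 0.24, adjusted p = 2.41e-23), PIF1 by -2.60 (SE 0.43, adjusted p = 3.83e-07) and CENPF, a kinetochore protein, by -2.18 (SE 0.23, adjusted p = 1.04e-17), and for TP53I3 by 1.82 (SE 0.33, adjusted p = 9.59e-06). Of 12885 genes, 165 passed, 21 higher and 144 lower, with 727 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 59 were lower and 16 were not called (74 lower adjusted over the list alone), with a median of -1.49 (adjusted p = 4.27e-240). Against siMYBL1 in U2OS, PIF1 differed by a further -3.81 (SE 0.34, adjusted p = 1.53e-25), CDCA3 by -3.48 (SE 0.28, adjusted p = 1.48e-31) and DLGAP5 by -3.02 (SE 0.24, adjusted p = 2.32e-31), and SYTL5 was higher by 2.29 (SE 0.60, adjusted p = 0.0114). There 227 of 14760 genes passed, 14 higher and 213 lower, with 1028 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 61 were lower and 14 were not called (68 lower adjusted over the list alone), with a median of -1.63 (adjusted p = 1.82e-263). The p53 targets lay higher in HCT116 (median 0.81, adjusted p = 3.25e-39) and U2OS (median 0.33, adjusted p = 0.000221). Stress genes lay lower in HCT116 (median -0.17, adjusted p = 0.00265) and U2OS (median -0.42, adjusted p = 1.67e-07), as did cholesterol synthesis genes (median -0.36, adjusted p = 1.82e-07 and median -0.42, adjusted p = 5.23e-07). Interferon-stimulated genes lay higher (median 0.21, adjusted p = 0.00252 and median 0.42, adjusted p = 2.82e-05). The G1/S list lay lower in HCT116 (median -0.48, adjusted p = 5.51e-25) and higher in U2OS (median 0.24, adjusted p = 4.69e-07). MYBL1 differed from its level after siMYBL1 alone by -0.18 (SE 0.49, adjusted p = 1) in HCT116 and -0.22 (SE 0.45, adjusted p = 1) in U2OS. With a correlation of 0.5 assumed between fold changes that share controls, the counts against siMYBL2 were 235 in HCT116 (70 higher and 165 lower) and 636 in U2OS (311 higher and 325 lower). Against siMYBL1 they were 533 in HCT116 (140 and 393) and 810 in U2OS (216 and 594).

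The double knockdown was also set against the sum of both single log2 fold changes. PLK1 departed from that sum by -1.50 (SE 0.29, adjusted p = 0.000754) in HCT116 and -2.62 (SE 0.33, adjusted p = 1.45e-11) in U2OS, KIF20A by -1.73 (SE 0.32, adjusted p = 0.000165) and -2.25 (SE 0.30, adjusted p = 2.17e-10), and CENPF by -1.62 (SE 0.28, adjusted p = 3.84e-05) and -1.65 (SE 0.32, adjusted p = 0.000236). In HCT116, 18 of 12873 genes passed, 1 higher and 17 lower, with 145 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 13 were lower and 62 were not called (51 lower adjusted over the list alone), with a median of -0.91 (adjusted p = 1.47e-185). In U2OS, 31 of 14701 genes passed, and all 31 were lower, with 200 at an unadjusted p under 0.05; for the G2/M list, of 75 listed members, 26 were lower and 49 were not called (47 lower adjusted over the list alone), with a median of -0.84 (adjusted p = 1.32e-171). The G1/S list lay below the sum in HCT116 (median -0.28, adjusted p = 3.22e-17) and above it in U2OS (median 0.41, adjusted p = 3.06e-26). The p53 targets lay above the sum in HCT116 (median 0.47, adjusted p = 2.54e-34). In U2OS the p53 list had a mean of -0.04 and did not pass (adjusted p = 0.976). Outside these lists, mitochondrially encoded genes lay below the sum in HCT116 (median -0.23, adjusted p = 0.0106) and U2OS (median -0.26, adjusted p = 0.00206; adjusted p = 0.164 on log2 fold changes). Cholesterol synthesis genes lay below it in HCT116 (median -0.20, adjusted p = 0.000137). Stress genes lay below it in U2OS (median -0.25, adjusted p = 5.53e-07). So did MYB family, MuvB and DREAM subunits in HCT116 (median -0.12, adjusted p = 0.0388; adjusted p = 0.101 with a correlation of 0.05 and 0.162 on log2 fold changes). Histone genes lay above it in HCT116 (median 0.22, adjusted p = 0.0325; adjusted p = 0.0872 with a correlation of 0.05). Interferon-stimulated genes lay above it in U2OS (median 0.19, adjusted p = 0.0319; adjusted p = 0.171 with a correlation of 0.05 and 0.0649 on log2 fold changes). This comparison from the tables was added after the data were examined, since the planned fit needs values per library. Its standard error adds the variances of all 3 fold changes. The shared controls do not cancel in it. A shift of the siCtrl libraries would move all 3 fold changes 1 way and the departure the other way. Mitochondrially encoded genes had medians above 0 in all 3 comparisons with siCtrl in each line, so their departure cannot be told apart from such a shift. Nor can those of the G1/S list in U2OS and of histone genes in HCT116, which lay above the sum. Against siCtrl their medians were below 0 after siMYBL1, siMYBL2 and both. They were -0.40, -0.14 and -0.12 for the G1/S list in U2OS, and -0.74, -0.50 and -0.02 for histone genes in HCT116.

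Within a line the 3 comparisons share the siCtrl libraries, which alone would give correlated fold changes. Across genes, which are not independent replicates, Pearson's r between the siMYBL2 and double knockdowns was 0.671 in HCT116 and 0.692 in U2OS, against 0.495 and 0.496 in simulated unchanged groups. The covariances were 0.0877 and 0.189, against simulated values of 0.0401 and 0.0635. Of 112 and 531 genes lower in these HCT116 comparisons, 99 were lower in both, where independent lists would share 4.63; in U2OS 383 of 543 and 1013 were shared, against 35.6. For siMYBL1 and the double knockdown r was 0.491 in HCT116 and 0.632 in U2OS, with simulated values of 0.493 and 0.495 and covariances of 0.0550 and 0.170 against 0.0401 and 0.0553. The lower genes shared by siMYBL1 and the double knockdown numbered 15 in HCT116, against 0.949 for independent lists, and 212 in U2OS, against 22.9. Between siMYBL1 and siMYBL2 r was 0.197 in HCT116 and 0.297 in U2OS, below the simulated 0.495 and 0.496. Here the covariances were 0.0186 and 0.0555 against simulated values of 0.0487 and 0.0526, a difference of -0.0301 in HCT116 and 0.00290 in U2OS. The simulation took the deposited standard errors as the noise, split equally between controls and knockdown. Its values are a guide only as far as those errors hold. Why the HCT116 covariance lay below the simulated value was not tested. The single knockdowns shared 1 lower gene in HCT116, against 0.201 for independent lists, and 66 in U2OS, against 12.3. Higher genes shared by siMYBL2 and the double knockdown were 24 in HCT116 (1.04 for independent lists) and 188 in U2OS (18.04). Unchanged groups against the same controls shared at most 0.01 genes on average. The 2 control libraries of a line could not be split, and part of each excess is open to the shared controls.

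Both lines were then compared with each other, where no library is shared. After siMYBL1, 17 genes were lower in both lines, where independent lists would share 0.541; they included LMNB1, PPIC, PDCD5, GINM1 and MYBL1. COTL1 and MYC were higher in both, where 0.533 was the value for independent lists. After siMYBL2, 88 genes were lower in both lines (4.05 for independent lists) and 5 were higher (0.481), namely DRAXIN, GPRC5A, HOXA10, ITGA2 and VGF. In the double knockdown 311 genes were lower (37.2) and 144 higher (22.7) in both. Pearson's r across genes between lines was 0.261 after siMYBL1, 0.384 after siMYBL2 and 0.542 in the double knockdown, and Spearman's rho 0.393, 0.401 and 0.487. With a base mean of at least 100, r was 0.491, 0.503 and 0.644 and rho 0.483, 0.454 and 0.547. COTL1, MYC, GPRC5A, HOXA10, ITGA2 and VGF were named after their values were seen.

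By the test of the difference between lines, 8 of 13472 genes differed after siMYBL1 (645 at an unadjusted p under 0.05), 27 of 12566 after siMYBL2 (554) and 157 of 12388 in the double knockdown (1176). LMNB1 fell further in U2OS after siMYBL1, with a difference of -1.02 (SE 0.23, adjusted p = 0.0294). MYBL2 fell further in U2OS after siMYBL2, with a difference of -0.9999 (SE 0.26, adjusted p = 0.0493), and in the double knockdown, with -1.19 (SE 0.25, adjusted p = 0.000790). PLK1 differed by -1.88 (SE 0.30, adjusted p = 6.60e-07) in the double knockdown, CPA4 by -2.12 (SE 0.31, adjusted p = 3.30e-08) and CXCL8 by 4.09 (SE 0.66, adjusted p = 1.11e-06). For the G2/M list the U2OS minus HCT116 difference after siMYBL1 was lower than that of other genes (median -0.29, adjusted p = 1.86e-18), and in the double knockdown likewise (median -0.37, adjusted p = 3.69e-16). In the double knockdown, of 75 listed members, 10 were lower and 65 were not called (1 higher and 22 lower adjusted over the list alone). The G1/S list differed in opposite directions after siMYBL1 (median -0.33, adjusted p = 1.86e-18) and in the double knockdown (median 0.38, adjusted p = 9.13e-12). For the p53 list the difference passed after siMYBL1 (median 0.43, adjusted p = 1.18e-11) and not in the double knockdown, where its median was -0.11 (adjusted p = 0.583). For stress genes the U2OS value lay above that of HCT116 after siMYBL1 (median 0.53, adjusted p = 5.44e-15) and in the double knockdown (median 0.32, adjusted p = 2.21e-05).

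After the data were examined, the annotated 3′ UTRs of 9839 genes were searched for 7-base sequences (7-mers) carried by genes with lower values. After siMYBL1, GAACTTA ranked first of 15375 in both lines, with a regression t of -17.2 in HCT116 (adjusted p = 7.96e-62) and -16.8 in U2OS (adjusted p = 6.51e-59). Shares of carriers were taken over all genes of a table with an annotated 3′ UTR and a base mean of at least 100 in that table. After siMYBL1 in HCT116 these were 10637 genes, and 15 of the 22 lower ones (68.2%) carried GAACTTA, against 8.89% of all. In U2OS they were 11063 genes, and 105 of the 315 lower ones (33.3%) carried it, against 8.99% of all. The word was chosen on the HCT116 values, so its share among lower HCT116 genes is a description and not a test. After siMYBL2, CCTTACA ranked first in both lines, with t of -12.5 in HCT116 (adjusted p = 1.23e-31) and -11.5 in U2OS (adjusted p = 1.77e-26). It was carried by 30 of 110 lower genes (27.3%) in HCT116 and 90 of 467 (19.3%) in U2OS, against 7.60% of 10717 and 7.81% of 11182 genes with that base mean. Of the 17 genes lower in both lines after siMYBL1, 13 carried GAACTTA and all 17 carried the 6-mer AACTTA. The target MYBL1 was 1 of these 17, and its 3′ UTR held the 6-mer but not GAACTTA. Of 87 genes searched among those lower in both lines after siMYBL2, 27 carried CCTTACA and 47 the 6-mer CTTACA. Of all genes searched in HCT116 after siMYBL1, 3996 held AACTTA and 9364 lacked it. After siMYBL2 there, 3207 held CTTACA and 8725 lacked it. Other words passed too. After siMYBL1, 147 words passed as lower in HCT116, 48 in U2OS and 28 in both. After siMYBL2, 17 passed in HCT116, 17 in U2OS and 7 in both. ACGCCCA, which does not overlap CCTTACA, ranked 4 in HCT116 (t of -7.15) and 5 in U2OS (t of -6.43) after siMYBL2. The second 7-mer in both lines was AACTTAA after siMYBL1 and CTTACAA after siMYBL2. Named genes that held a second 7-mer, not marked above, included HMMR (AACTTAA), CKAP2L, CENPF, MKI67 and NEK2 (CTTACAA) and CDK1 (both).

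**Figure D3:**
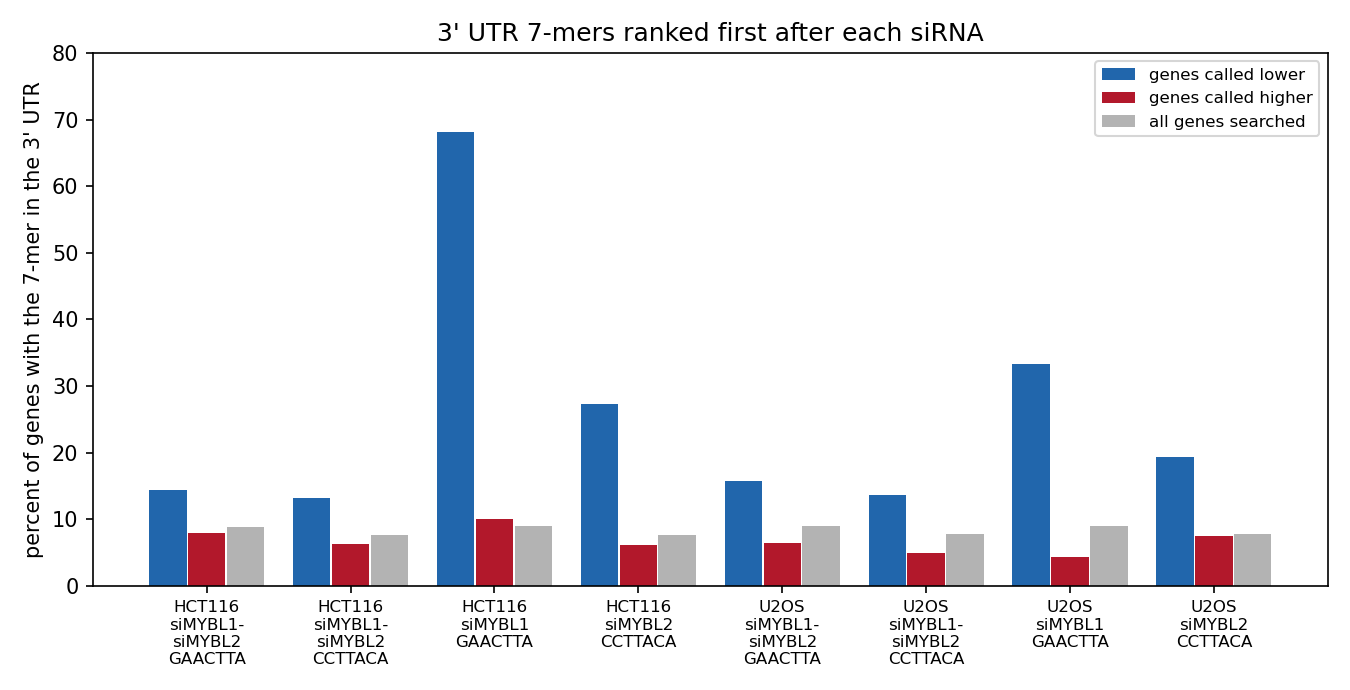
Share of genes, in percent, whose annotated 3′ UTR holds the 7-mer ranked first after each siRNA, among genes called lower, genes called higher and all genes searched with a base mean of at least 100. Each group of bars is 1 comparison with siCtrl and 1 7-mer. The share among lower genes was 68.2% in HCT116 after siMYBL1, against 8.89% of all genes with that base mean.

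Genes were then split, without a minimum base mean, by the 6-mer associated with the siRNA, or by either 6-mer in the double knockdown. Among genes with an annotated 3′ UTR that lacked it, 9 of 9364 passed after siMYBL1 in HCT116 (6 higher and 3 lower), 81 of 8725 after siMYBL2 (29 and 52) and 436 of 6733 in the double knockdown (203 and 233). Among those that held it, 4 were higher and 20 lower of 3996 after siMYBL1, 8 and 59 of 3207 after siMYBL2, and 133 and 290 of 4955 in the double knockdown. The remaining 3963, 1455 and 1197 genes were not searched. In U2OS 466 of 8700 genes without it passed after siMYBL1 (344 and 122), 474 of 9388 after siMYBL2 (180 and 294) and 1046 of 7772 in the double knockdown (643 and 403). With it, 130 were higher and 202 lower of 3932 after siMYBL1, 75 and 197 of 3546 after siMYBL2, and 408 and 513 of 5691 in the double knockdown. There 2131, 2544 and 3340 genes were not searched. Among the 42 G2/M genes with neither 6-mer, 41 were lower in the HCT116 double knockdown, with a median of -1.69, and all 42 in U2OS, with a median of -1.98. Of 56 G2/M genes without the 6-mer associated with siMYBL2, 23 were lower after siMYBL2 in HCT116 and 33 in U2OS, with medians of -0.55 and -0.65. Of 51 without the 6-mer associated with siMYBL1, 0 were lower after siMYBL1 in HCT116 and 19 in U2OS, and the medians were -0.20 in HCT116 and -0.49 in U2OS.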

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

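The tests of differences between lines were fixed before the data were examined, whereas the test on MYBL1 depth was chosen only after its result was seen. Each value stands here because the effect in U2OS differed from that in HCT116 by a test of the difference. It is U2OS minus HCT116 on the log2 scale. The numbers of genes that differed were 8 after siMYBL1, 27 after siMYBL2 and 157 in the double knockdown.

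Among lists after siMYBL1, the median difference was -0.29 for G2/M genes, -0.33 for G1/S genes, 0.51 for histone genes (adjusted p = 0.0183; adjusted p = 0.101 with a correlation of 0.05), 0.43 for p53 targets, 0.38 for cholesterol synthesis genes, 0.53 for stress genes and 0.51 for secretory genes. After siMYBL2 it was -0.12 for G2/M genes (adjusted p = 0.0160; adjusted p = 0.294 with a correlation of 0.05 and 0.300 on log2 fold changes), -0.91 for histone genes, -0.40 for epithelial markers and -0.63 for mesenchymal markers. The histone, epithelial and mesenchymal values rested there on 14, 5 and 9 members, and the histone mean was -0.54. In the double knockdown the median difference was -0.37 for G2/M genes, 0.38 for G1/S genes, -1.22 for histone genes, 0.30 for cholesterol synthesis genes, 0.32 for stress genes, 0.61 for secretory genes, -0.20 for mitochondrially encoded genes (adjusted p = 0.0497; adjusted p = 0.127 with a correlation of 0.05 and 0.234 on log2 fold changes) and -0.36 for epithelial markers. The histone value rested there on 11 members, with a mean of -0.64, and the epithelial value on 9.

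Among named genes, LMNB1 differed by -1.02 (SE 0.23) after siMYBL1. After siMYBL2, MYBL2 differed by -0.9999 (SE 0.26), DAP by -1.54 (SE 0.28), ESRG by -1.23 (SE 0.29) and H2AC6 by -1.65 (SE 0.41). In the double knockdown the G2/M genes AURKA, CDCA3, KIF20A, PIF1 and PLK1 lay lower in U2OS, with differences of -1.28 (SE 0.29), -1.48 (SE 0.32), -0.99 (SE 0.29), -1.47 (SE 0.41) and -1.88 (SE 0.30). MYBL2 differed there by -1.19 (SE 0.25), CPA4 by -2.12 (SE 0.31), DAP by -1.62 (SE 0.27), ESRG by -1.02 (SE 0.29), IFIT1 by -2.17 (SE 0.48), KRT18 by -0.89 (SE 0.24) and TP53I3 by -1.26 (SE 0.30). The histone genes H2AC6, H2BC12 and H2BC5 differed by -1.72 (SE 0.41), -1.22 (SE 0.34) and -1.60 (SE 0.45). The 3′ UTR of H2BC5 held the 7-mer associated with siMYBL1. Higher in U2OS were CXCL8 by 4.09 (SE 0.66), DRAXIN by 2.07 (SE 0.57), DSCC1 by 0.96 (SE 0.27), KITLG by 1.63 (SE 0.32) and TRIB3 by 1.48 (SE 0.31).

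After siMYBL1, 843 genes passed in U2OS and 45 in HCT116. A deeper loss of MYBL1 in U2OS would put its U2OS minus HCT116 difference below 0; it was 0.69 (SE 0.44, adjusted p = 1), so the estimate lay on the other side, though the difference itself did not pass. Smaller standard errors in U2OS were argued against by their medians, 0.222 in U2OS and 0.187 in HCT116, and by the variance of the fold changes beyond their squared errors, 0.132 in U2OS and -0.00531 in HCT116. Without genes with a standard error of 2 or more, H2AC19 among them, these variances were 0.0902 and -0.00237. A difference between the lines in their response to MYBL1 loss, or to the siRNA itself, may remain; these were not tested against each other.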

How the results depend on the processing

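Alternatives that need values per library were not run: another count tool, other normalizations, no filter or a stricter one, fits of 4 libraries, a replicate block, leaving out each replicate, pseudocounts, camera with an estimated correlation, fry and an interaction fit. No paired analysis was possible because the tables hold no values per library. With adjusted p under 0.01 the genes changed after siMYBL1, siMYBL2 and both numbered 24, 88 and 506 in HCT116 and 418, 458 and 1352 in U2OS; those differing between lines numbered 1, 9 and 60. For the double knockdown against siMYBL2 they were 53 in HCT116 and 105 in U2OS. With an absolute log2 fold change of at least 1 the counts against siCtrl were 16, 50 and 292 in HCT116 and 294, 320 and 949 in U2OS. Fewer genes pass a stricter threshold by construction. Among genes searched that lacked the 6-mer associated with the siRNA, chosen after seeing the data, they were 9 (6 higher, 3 lower), 81 (29 and 52) and 436 (203 and 233) in HCT116, and 466 (344 and 122), 474 (180 and 294) and 1046 (643 and 403) in U2OS; carriers of the 6-mer were left out, as were genes without a searched 3′ UTR (3963, 1455 and 1197 in HCT116 and 2131, 2544 and 3340 in U2OS). With a correlation of 0.5 between fold changes, also chosen after seeing the data, the double knockdown against siMYBL2 gave 235 (70 higher, 165 lower) in HCT116 and 636 (311 and 325) in U2OS, and against siMYBL1 533 (140 and 393) and 810 (216 and 594); the smaller error follows from the assumed correlation. With a base mean of at least 100 the correlations between lines were 0.491, 0.503 and 0.644, for siMYBL1, siMYBL2 and both; the cause was not tested. Of 8 lists called in HCT116 after siMYBL1, the number was 4 with a list correlation of 0.05, 3 on log2 fold changes and 5 among genes searched without the 6-mer, where the cholesterol and stress lists lost the call and mitochondrially encoded genes, not searched in any comparison, were not tested. On log2 fold changes the G2/M, histone and secretory lists passed there, and the mitochondrial, G1/S, ribosomal, cholesterol and stress lists did not. In U2OS it was 4 with a correlation of 0.05 in place of 7 after siMYBL2, and 5 on log2 fold changes in place of 9 in the double knockdown, where the G1/S, stress, ribosomal and mesenchymal lists lost the call. For the departure from additivity in U2OS it was 3 on log2 fold changes in place of 5, with the interferon and mitochondrial lists lost. The G2/M difference between lines after siMYBL2 had adjusted p = 0.294 with a correlation of 0.05 and adjusted p = 0.300 on log2 fold changes. The histone list after siMYBL2 in HCT116 turned downward on log2 fold changes (adjusted p = 0.00457); the cause was not tested. Of the other list results, departures from additivity included, 22 lost the call on log2 fold changes and 2 gained it, and 25 lost it with a correlation of 0.05. Among genes searched without the 6-mers, 5 lost it and 5 gained it. In the HCT116 double knockdown 6 lists passed there in place of 9, with MuvB, interferon and mesenchymal lists lost, the epithelial list gained and the mitochondrial list again not tested. On ranks 15 further list results passed, 1 lost the call and 0 turned direction. At a base mean of at least 10, all 340 results for named single genes kept their side of the threshold. At a base mean of at least 100, 319 did, and 2 others passed in addition. The list tests were not repeated at these minimum base means. The depth of single libraries is unknown, so its limits could not be given.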

Other observations

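The tests of MYBL2 depth, of G1/S genes and of CCTTACA in U2OS, the search for 7-mers and the departure from additivity itself were chosen only after the result was seen. Several named genes of mitosis were called below the sum of the single knockdowns in both lines. TOP2A lay at -1.33 (SE 0.26) in HCT116 and -1.637 (SE 0.28) in U2OS, DLGAP5 at -1.43 (SE 0.32) and -1.61 (SE 0.29), CKAP2L at -1.67 (SE 0.35) and -1.48 (SE 0.37), CDCA3 at -1.71 (SE 0.38) and -2.40 (SE 0.33), AURKA at -1.25 (SE 0.31) and -1.78 (SE 0.34), and PRR11 at -1.83 (SE 0.29) and -1.46 (SE 0.29).

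The G2/M list departed from the sum of the single knockdowns by a median of -0.91 in HCT116 and -0.84 in U2OS. A deeper loss of MYBL2 RNA in the double knockdown was argued against in both lines. MYBL2 differed from siMYBL2 alone by 0.13 (SE 0.25) in HCT116 and -0.062 (SE 0.25) in U2OS. MYBL1 stood at -1.85 in the double knockdown and -1.67 after siMYBL1 alone in HCT116, and at -1.20 and -0.98 in U2OS. These estimates lay lower in the double knockdown by less than their standard errors, so a deeper loss of MYBL1 stays open. In U2OS the median departure of the G1/S list was 0.41, above the sum. Its medians against siCtrl were -0.40 after siMYBL1, -0.14 after siMYBL2 and -0.12 in the double knockdown. A shift of the siCtrl libraries would also give such signs, so this departure cannot decide on a like fall of all cell cycle genes. In HCT116 that list lay below the sum, as did the G2/M list, with a smaller median departure of -0.28. Its changes after the single knockdowns were smaller there too. A like fall therefore stays open in both lines. Seed matches of the siRNAs in the 3′ UTRs of the G2/M genes themselves were argued against by the 42 members with neither 6-mer, whose median departures were -0.95 and -0.96. The 42 members bear only on matches in their own 3′ UTRs. Effects passed on from other genes that hold the 6-mers were not tested, nor were other causes. No value here separates a joint need for MYBL1 and MYBL2 at these genes from an indirect change in the share of cells in G2 and mitosis. That share was not measured, so both stay open.

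Of 17 genes lower after siMYBL1 in both lines, 13 held GAACTTA in the 3′ UTR, LMNB1, PPIC and PDCD5 among them, and genes with CCTTACA lay lower after siMYBL2. Off-target matches of the siRNA seeds may account for part of these falls: GAACTTA, ranked first in HCT116 with t of -17.2, had t of -16.8 in U2OS, and CCTTACA, with t of -12.5 in HCT116, had t of -11.5 in U2OS. A seed match would also stand in the target itself, and 3 of 6 annotated MYBL1 transcripts held GAACTTA, the longest at 2 sites (0.317 by chance), and 2 of 2 annotated MYBL2 transcripts CCTTACA, the longest at 1 site (0.165 by chance). The siRNA sequences are not given in the sources used here, so the matches themselves were not seen, and no biological explanation was tested. Whether falls of the carriers follow from loss of the targets stays open.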
